A study of Mus musculus with 7 samples.

How the data were processed

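The series holds 7 RNA-seq libraries of muscularis macrophages from C57BL6/J mice, 4 after sham surgery and 3 after pMCAO surgery, all at 24 h. Per the labels' protocols, 2.0 ng of total RNA entered each library, ribosomal RNA was removed by cleavage, libraries were made with the Trio RNA-seq kit and sequenced as paired 100 base reads on a NextSeq 2000, at a stated depth of about 35 M reads per sample. Groups and replicate numbers came from the sample titles. Low RNA input needs strong amplification, and reads without molecular identifiers are not independent molecules, so counts of a single library overstate its precision and the spread between libraries was used as the error.

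A single deposited table held all values used. The read counts per gene in it were made by the authors, with STAR and featureCounts for GRCm38 (mm10) and with limma named per the submitters' processing notes, without versions or settings. The strand setting and the annotation release of the counting are not given in the sources used here, so genes that overlap another gene (Igtp and Irgm2) or have near-identical copies (class I genes, histones, Cd209 lectins) are uncertain. The deposited CPM values equal the count divided by the library's total in the table, with no scaling factor, to within 0.0005. The log2 fold changes and the mean log2 expression per gene in the deposited table are the authors', as are the p-values and the FDR, which equals the Benjamini-Hochberg adjustment of the p-values. The table lists 17209 genes, each above 0.5 CPM in at least 4 of the 7 libraries, so a gene expressed only in the 3 pMCAO libraries would not be listed. No library had an unmapped column and no listed gene lacked a name.

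All results other than those of the authors' deposited table were computed from the counts as deposited. The test was the edgeR (4.0.16) quasi-likelihood F test in R 4.3.3, with robust dispersion estimates, TMM factors, the edgeR expression filter by group, which kept all 17209 genes, and group as the only term. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 43.6%. CPM values in the text are after TMM scaling, as mean ± SD over 4 sham and 3 pMCAO libraries, and log2 changes are pMCAO minus sham. The standard error of a log2 change is its size divided by the square root of the F statistic. A count of 3 in a library corresponds to 0.087 CPM in Sham 4 and 0.236 CPM in pMCAO 1, which covers counting error only.

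Gene lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01. There were 31 program lists, all tested, and 26 lists of cell type markers and RNA quality, of which 23 were tested. Adjustment was separate for each kind, over lists with at least 5 measured members (programs) or 3 (markers). Camera compares a list with the other genes. It was repeated with an estimated correlation, with which 0 program lists and 0 marker lists passed. It was also repeated with fry, which asks whether the members move, on balance, in a single direction, and with which 0 of either kind passed. By the fry test for change in either direction many program lists passed, among them the resident muscularis list (adjusted p = 0.00261). The list counts per gene are given over all genes and adjusted over the list alone. A list score is the mean log2 CPM of the members in a library minus the mean over sham libraries. Single values per library were compared with two-sided exact permutation tests, which cannot go below p = 0.057 for 4 against 3 libraries.

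Gene positions are those of GENCODE M21 (GRCm38), which holds 99.5% of the gene identifiers on the same chromosome. GC content and exon length came from the same annotation. Genes were named by a rule. It took genes past the threshold with a mean of at least 5 CPM and no overlap between groups, up to 12 per direction, then, in a direction with fewer, up to 6 genes with the smallest p. It added the 3 members of each list with the smallest p, and 7 genes that check the sorted population. Genes called by the authors' deposited table alone (H2-Ab1, mt-Rnr2 and Ccl5) are outside the rule and were chosen after their values were seen. Results for some genes are not reported here.

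The design, the gene lists, the rule for named genes and 22 alternative settings were fixed before the data were examined. These cover normalization, filters, other tools (DESeq2 1.42.0, limma-voom), a replicate block, leaving out each library, thinning of counts, a composition filter, the threshold and the list test. After seeing the data, 4 settings were added: offsets for each library's trend with GC content and exon length (mgcv 1.9.3), Y-linked counts as a covariate, a score of fibroblast and blood endothelial markers as a covariate, and a library block of 4 levels inferred from the authors' deposited fold changes. A result under another setting counts as reversed when the direction differs and at least 1 of the 2 fits passes the threshold, and as the same when neither passes.

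The procedure was tested on simulated data for this comparison of 4 against 3 libraries, with 16989 genes passing the filter. It recovered 38 of 100 genes changed 2-fold and 85 of 100 changed 4-fold. It called 4 of 16763 unchanged genes, and the simulated list together with 1 unchanged marker list. The 2-fold and 4-fold changes were set in genes with a mean of at least 5 CPM. Counts were drawn for each gene apart, without library trends, blocks or correlation between genes. The calls among unchanged genes and lists therefore do not give error rates for the real libraries. All pairs of libraries differed by far more than sampling noise, the lowest chi-square per degree of freedom being 30.1. Pearson correlations of log2 CPM were 0.917 to 0.954 within sham libraries, 0.888 to 0.925 within pMCAO libraries and 0.891 to 0.926 between groups. Of all genes, 12.6% had no overlap between groups, against 5.71% by chance.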

Results

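The series measured the transcriptome of muscularis macrophages, the resident macrophages that lie among the smooth muscle and the nerves of the gut wall. The muscle layer was peeled from the mouse small intestine 24 h after surgery and cells carrying GFP at the Cx3cr1 fractalkine receptor locus were sorted. The groups were 4 libraries after sham surgery (Sham 1 to Sham 4) and 3 libraries after pMCAO surgery (pMCAO 1 to pMCAO 3), which the title of the series calls stroke. Counts assigned to the listed genes were 19238209, 22425640, 18873893 and 34432716 in Sham 1 to Sham 4 and 12685941, 21680302 and 18779472 in pMCAO 1 to pMCAO 3. The comparison asked which genes of these macrophages differed after stroke. The labels do not say whether each library came from a single animal, and the description of pMCAO 3 names a pool, so the p-values measure the spread between these samples.

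After pMCAO, 17 of 17209 genes changed, of which 12 were higher and 5 lower than after sham surgery. The largest rise was that of Hif3a, a member of the hypoxia-inducible factor family that glucocorticoids also induce, from 6.0 ± 4.13 CPM (SD, n = 4) to 103 ± 15.7 CPM (SD, n = 3). Zbtb16, a zinc finger transcription factor induced by glucocorticoids, rose from 23.4 ± 7.90 to 73.6 ± 10.6 CPM, and Gpx3, the secreted glutathione peroxidase, rose from 34.6 ± 4.40 to 110 ± 29.8 CPM. H2-Eb1, a beta chain of the class II antigen-presenting molecule, fell from 1709 ± 533 to 497 ± 211 CPM, and Ciita, the master regulator of class II genes, fell from 159 ± 12.6 to 75.9 ± 4.55 CPM. Mgl2, a C-type lectin of alternatively activated macrophages, fell from 268 ± 45.3 to 119 ± 17.1 CPM, and Mmp13, a collagenase, fell from 139 ± 17.4 to 49.8 ± 5.81 CPM.

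On the log2 scale Hif3a changed by 4.12 (SE 0.46, adjusted p = 0.00631 by the edgeR quasi-likelihood test, as for each gene here). The gene (ENSMUSG00000004328) lies on chromosome 7 from 17031507 to 17062427 of GRCm38. Zbtb16 (ENSMUSG00000066687, chromosome 9, 48654297 to 48836222) changed by 1.66 (SE 0.26, adjusted p = 0.0240) and Gpx3 (ENSMUSG00000018339, chromosome 11, 54902453 to 54910377) by 1.67 (SE 0.22, adjusted p = 0.00631). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) changed by -1.78 (SE 0.29, adjusted p = 0.0319). Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331) changed by -1.49 (SE 0.19, adjusted p = 0.00631). Nxpe5 (ENSMUSG00000047592, chromosome 5, 138225898 to 138253363) fell from 137 ± 31.2 to 40.4 ± 6.95 CPM, a log2 change of -1.76 (SE 0.22). The smaller changes of Mgl2 (-1.17, SE 0.19) and Ciita (SE 0.17) had adjusted p of 0.0274 and 0.0240. The other 9 genes that rose were Peg3 (log2 change 2.99), Sox17 (2.78), Strip2 (2.08), Ghr (2.07), Prex2 (2.04), Nid1 (1.92), Abca6 (1.78), Egfr (1.52) and Adgrg6 (1.16). Sox17 is a transcription factor of endothelium, Nid1 a basement membrane glycoprotein, and Ghr and Egfr the receptors of growth hormone and of epidermal growth factor. For each of the 17 genes the sham and pMCAO values did not overlap. Nid1 was at 11 ± 1.08 CPM in sham libraries and 41.5 ± 1.8 CPM after pMCAO. Lower genes that just missed the threshold included Ccl12, a monocyte chemoattractant (-1.59, adjusted p = 0.0504), the lectin Cd209f (-2.08, adjusted p = 0.0524) and Cd74, the invariant chain of class II molecules (-1.45, adjusted p = 0.0527). Others were the interferon regulator Irf7 (adjusted p = 0.0527), Fcrls (-1.09, adjusted p = 0.0537) and Tcof1 (-1.15, adjusted p = 0.0574). All of these are lower because the naming rule added such genes only in the direction with fewer calls. Higher genes lay as near, such as Prg4 (2.00, adjusted p = 0.0535). At an adjusted p under 0.10, 65 genes were higher and 33 lower.

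**Figure D1:**
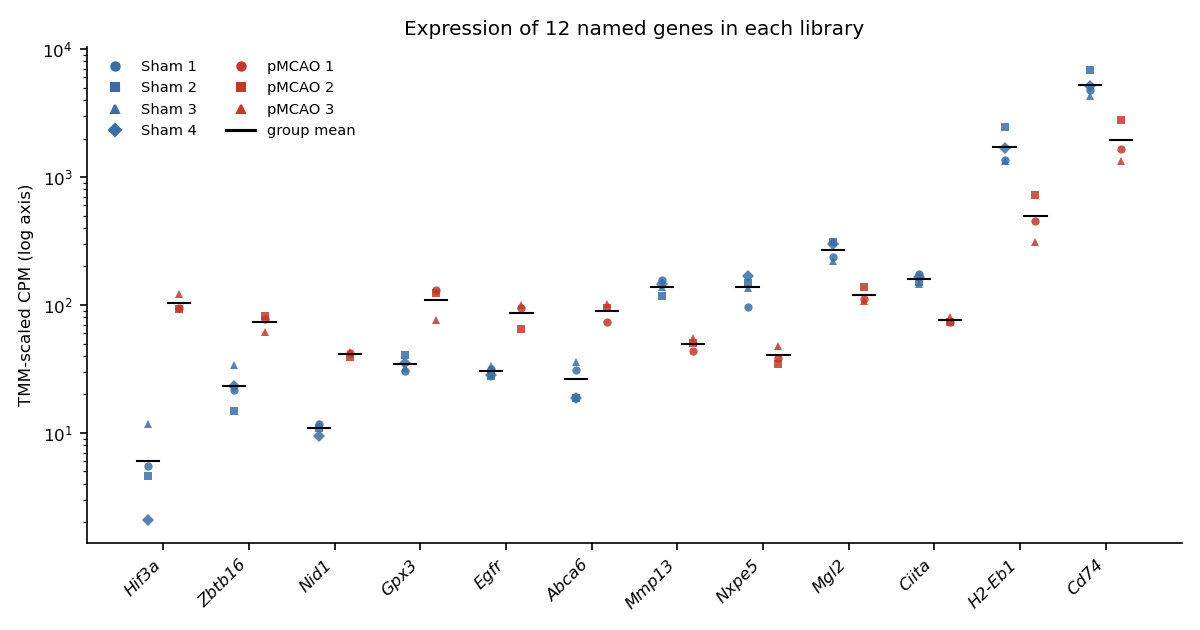
CPM after TMM scaling (log axis) of 11 changed genes and of Cd74 in each of the 4 sham libraries (blue) and 3 pMCAO libraries (red), with a bar at each group mean. For each gene the values of the groups do not overlap, and for Hif3a the means are 6.0 and 103 CPM.

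The count depended on the setting and on single libraries. It was 476 with DESeq2, 818 with limma-voom and sample quality weights, and 75 over genes of at least 5 CPM. It was 43 after thinning to the smallest library, 38 with Y-linked counts as a covariate, 35 with limma-voom, 34 with upper-quartile factors and 28 with offsets for GC content and exon length. Leaving out libraries, it was 47 without Sham 1, 47 without Sham 2, 9 without Sham 4, 0 without pMCAO 1 (where 1987 genes had an unadjusted p under 0.05 by edgeR), 100 without pMCAO 2 and 7 without pMCAO 3. Without pMCAO 1 the median absolute log2 change of the 17 genes was 1.73, against 1.78 over all libraries. All 17 kept their direction with an unadjusted p under 0.05. This is no independent support, as they were chosen from the same libraries with no overlap between groups. Leaving out a library could therefore not turn their direction. Without scaling factors 29 genes passed, 14 higher and 15 lower, with the median of all genes shifted to -0.14 from -0.02. Library blocks inferred from the authors' deposited fold changes set Sham 2 as the only sham library against pMCAO 1 and pMCAO 3. Within them the median absolute log2 change of the 17 genes was 1.96, and their direction could likewise not turn. Only H2-Eb1 of the 17 passed there (log2 change -2.70, SE 0.28, adjusted p = 0.0340). With a score of fibroblast and endothelial markers (the stromal marker score) as a covariate 0 genes passed (969 at an unadjusted p under 0.05 by edgeR). All 17 kept their direction there, 15 of them with an unadjusted p under 0.05, at a median absolute log2 change of 1.60. The exceptions were Prex2 and Sox17, with log2 changes of 0.72 (SE 0.45) and 1.59 (SE 0.81). The stromal marker score itself separated the groups, at -0.37 to 0.64 in sham libraries and 0.78 to 1.77 after pMCAO. As a covariate it widens the SE, for the glucocorticoid list score from 0.20 to 0.43 between libraries. The lost calls therefore cannot tell stromal RNA from an effect of pMCAO.

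Most genes of antigen presentation and of the type I interferon response had lower means after pMCAO, and 2 of them passed over all genes. Of 14 measured genes of class II antigen presentation, 12 had lower means and the median log2 change was -1.11. Of these, 2 (Ciita and H2-Eb1) fell by the test over all genes and 8 fell when adjusted over the list alone, and none rose. Cd74 was at 5272 ± 1158 CPM in sham libraries and 1935 ± 775 CPM after pMCAO. Of 16 genes of class I presentation, 13 fell when adjusted over the list alone and 0 over all genes, with a median log2 change of -0.72. Psmb10, a catalytic subunit of the immunoproteasome, went from 87.7 ± 22.2 to 40.4 ± 13.8 CPM. H2-Q4 was at 131 ± 22.4 and 78.8 ± 16.4 CPM, and its counts are uncertain because close paralogs could share its reads.

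Of 30 genes of the type I interferon response, 28 had lower means and 11 fell when adjusted over the list alone, against 0 over all genes. Irf7, the regulator that amplifies the response, went from 49.5 ± 20.4 to 14.7 ± 3.89 CPM (log2 change -1.75, SE 0.32), Bst2 (tetherin) from 140 ± 30.9 to 60.3 ± 21.1 CPM and Oasl1 from 10.2 ± 3.36 to 2.68 ± 0.648 CPM. Of the 18 measured GTPases and partners induced by interferon-gamma, 0 passed over all genes or when adjusted over the list alone, and the median log2 change was -0.35. As sets, the class II list (camera, adjusted p = 3.44e-09), the class I list (adjusted p = 1.84e-09), the type I interferon list (adjusted p = 1.87e-12) and the interferon-gamma list (adjusted p = 0.0282) lay lower than the other genes. With an estimated correlation the adjusted p were 0.218, 0.264, 0.218 and 0.760 in that order. Within the inferred library blocks, where Sham 2 is the only sham library, the first 3 lists had medians of -1.89, -1.20 and -0.41 and adjusted p of 4.71e-12, 4.71e-12 and 0.00400, and the interferon-gamma list had a median of -0.27 (adjusted p = 0.0592). The interferon-gamma call was also lost without Sham 1 (adjusted p = 0.321), Sham 2 (0.110) or pMCAO 2 (0.614) and with Y-linked counts as a covariate (median -0.31, adjusted p = 0.132), and its direction turned with sample quality weights (0.816). All 14 class II and all 30 type I interferon genes were at 5 CPM or more in sham libraries, and markers of fibroblasts and the mitochondrial ribosomal RNA share were higher in the same pMCAO libraries. The class I median was -0.45 with offsets for GC content and exon length, and with the stromal marker score as a covariate the type I interferon and interferon-gamma medians were -1.06 and -1.22.

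Most genes of the glucocorticoid response had higher means after pMCAO. Of 26 measured members, 22 had higher means, 2 rose over all genes (Hif3a and Zbtb16), 15 rose when adjusted over the list alone and none fell by either, with a median log2 change of 0.92. Klf9, a target of the glucocorticoid receptor, was at 42.4 ± 14.9 CPM in sham libraries and 120 ± 50.5 CPM after pMCAO (log2 change 1.5, SE 0.30, adjusted p = 0.0614). The list lay higher than the other genes by camera (adjusted p = 4.49e-11). The adjusted p was 0.210 with an estimated correlation and 0.000469 within the inferred library blocks, which hold 1 sham library against 2 and gave a median of 0.79. The same pMCAO libraries had fibroblast marker scores of 2.12, 0.48 and 1.99 and mitochondrial ribosomal RNA shares of 12.6%, 8.26% and 8.84%, above those of all sham libraries.

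A further 3 lists, which share Per1, Thbs1 or Dusp1 with it, had smaller positive medians and calls that depended on the setting. Of 21 genes of the cAMP and adrenergic response, 17 had higher means and the median log2 change was 0.32 (camera adjusted p = 0.00140, and adjusted p = 0.218 with an estimated correlation). Thbs1, the matricellular protein thrombospondin-1, was at 53.1 ± 35.5 and 275 ± 155 CPM. Of 27 immediate early genes the median was 0.22 (adjusted p = 0.0303, and adjusted p = 0.632 with an estimated correlation), led by Fosl2, a subunit of AP-1, at 54.1 ± 7.0 and 84.7 ± 15.6 CPM, Klf4 and Atf3. Of 18 circadian clock genes the median was 0.23 (adjusted p = 0.0282, and adjusted p = 0.223 with an estimated correlation), led by the repressor Nr1d2 at 74.1 ± 11.7 and 116 ± 24.8 CPM. In these 3 lists 0 members passed over all genes or when adjusted over the list alone. The calls were lost without pMCAO 2 (adjusted p of 0.0561, 0.988 and 0.150 in that order), for the immediate early list also without Sham 1 (0.0889) or Sham 3 (0.115), and for the clock list without Sham 2 (0.0535) or with the stromal marker score as a covariate (median 0.20, adjusted p = 0.0690). With Y-linked counts as a covariate the immediate early (0.156) and clock (median 0.20, adjusted p = 0.110) calls were lost, as they were with sample quality weights (0.565 and 0.0815), and so were the clock call over genes of at least 5 CPM (0.0765) and the immediate early call without scaling factors (0.0951). The immediate early median was 0.43 (adjusted p = 3.60e-11) with offsets for GC content and exon length, 0.50 (adjusted p = 0.000935) with the stromal marker score and 0.09 with Y-linked counts. Within the inferred library blocks, with 1 sham library against 2, no call held, with a median as large for cAMP (0.33, adjusted p = 0.0755), turned for immediate early genes (-0.09, 0.997) and larger for the clock (0.43, 0.0864).

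**Figure D2:**
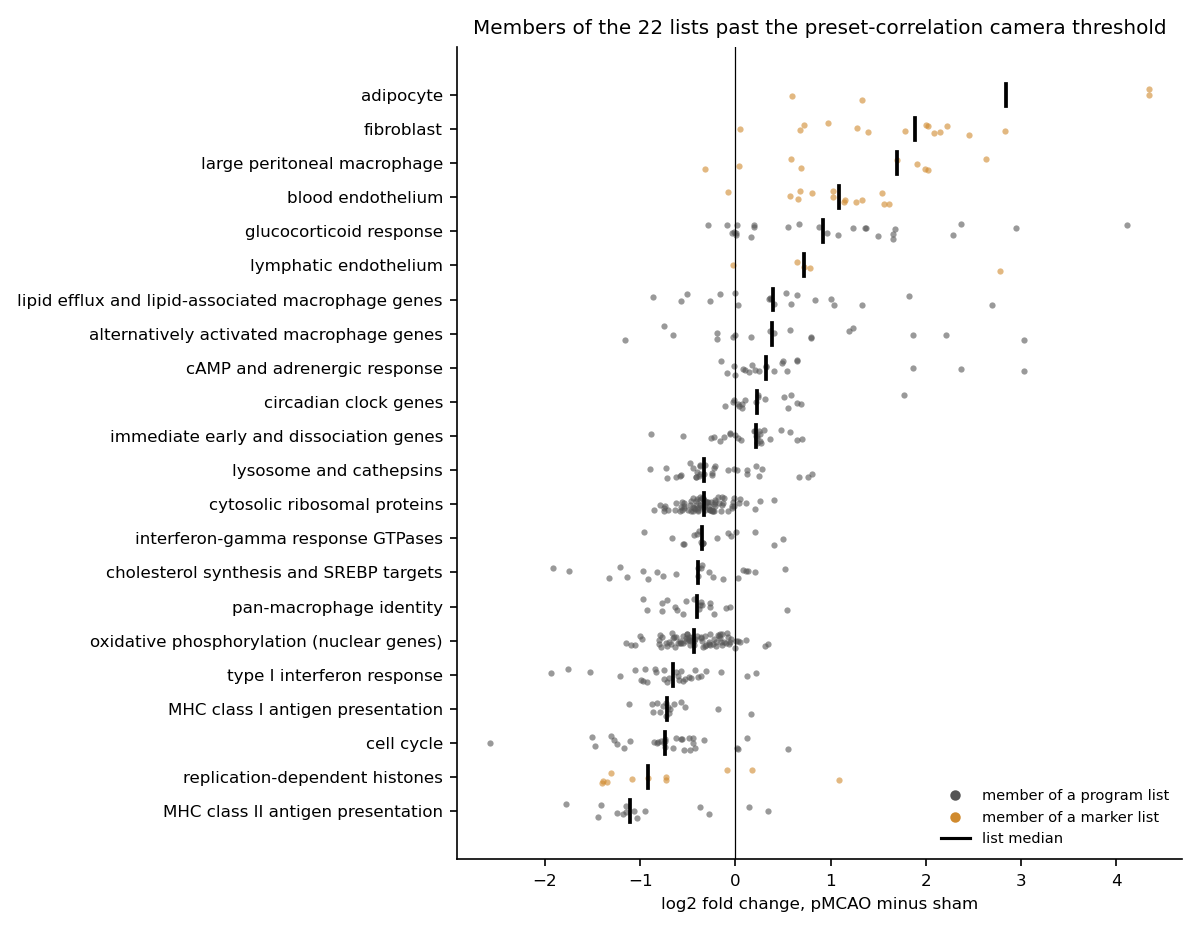
Log2 fold change, pMCAO minus sham, of each measured member (points, grey for program lists and orange for marker lists) of the 22 gene lists past the camera threshold with the preset correlation, with a bar at each list's median. The class II list has the lowest median of the program lists, -1.11, and the glucocorticoid list the highest, 0.92.

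Most genes that mark macrophages in general had lower means, while those of the resident muscularis population went both ways. Of 20 pan-macrophage genes, 19 had lower means, 8 fell and 1 rose when adjusted over the list alone and 0 passed over all genes, with a median log2 change of -0.41 (camera adjusted p = 1.13e-07, and adjusted p = 0.264 with an estimated correlation). Within the inferred blocks the median was -0.76 (adjusted p = 3.93e-09), but there Sham 2, the sham library with the highest pan-macrophage score (0.17), is the only one. The median was -0.25 with offsets for GC content and exon length and -0.61 with the stromal marker score as a covariate. Fibroblast markers and the mitochondrial ribosomal RNA share were higher in the same pMCAO libraries. C1qa and C1qb, chains of complement C1q, went from 546 ± 104 to 279 ± 76.9 CPM and from 3125 ± 647 to 1646 ± 542 CPM. The reporter locus Cx3cr1 had a log2 change of -0.55 (adjusted p = 0.256), Csf1r, the receptor of the macrophage growth factor, -0.35 (0.496), Adgre1, which encodes F4/80, -0.36 (0.484), Cd68 -0.23 (0.722), the Fc receptor Fcgr1 -0.77 (0.149), the efferocytosis receptor Mertk 0.54 (0.272) and the pan-leukocyte gene Ptprc -0.02 (0.981). None of these 7 passed over all genes, while Cx3cr1 and Fcgr1 fell and Mertk rose when adjusted over the pan-macrophage list alone. Of 22 resident muscularis genes, 4 rose and 5 fell when adjusted over the list alone and 0 passed over all genes. Cd209f and Cd209b were at 15.5 ± 4.78 and 8.75 ± 2.74 CPM in sham libraries against 3.66 ± 0.326 and 1.25 ± 0.753 CPM, and the scavenger receptor Colec12 at 26.4 ± 5.80 against 56.5 ± 11.5 CPM. The list did not move as a set (median log2 change -0.01, mean -0.27, camera direction up, adjusted p = 0.878).

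Alternatively activated macrophage genes were mixed. Their list scores were 0.51, 1.10 and -0.24 in pMCAO 1, 2 and 3. The library pMCAO 2 also had the highest scores of adipocyte (4.07) and large peritoneal macrophage (1.73) markers. Of 18 members, 3 rose and 2 fell when adjusted over the list alone and Mgl2 fell over all genes, with a median log2 change of 0.38 (camera adjusted p = 0.0451, and adjusted p = 0.697 with an estimated correlation). Clec7a, the beta-glucan receptor Dectin-1, was at 110 ± 22.7 and 192 ± 43.1 CPM, and Il4ra, a chain of the interleukin-4 receptor, at 172 ± 19.4 and 102 ± 26.7 CPM. This call was lost without Sham 3 (adjusted p = 0.0935), Sham 4 (0.104) or pMCAO 2 (0.863), over genes of at least 5 CPM (0.108), with sample quality weights (0.146), after thinning (0.0681) and with Y-linked counts as a covariate (median 0.25, adjusted p = 0.495). With the stromal marker score the median was 0.72 (adjusted p = 0.00162), and the direction of the test turned within the inferred library blocks (median 0.19, adjusted p = 0.824), where Sham 2 is the only sham library. Of 19 chemokines, 2 rose and 3 fell when adjusted over the list alone and 0 passed over all genes. Cxcl2, a neutrophil chemoattractant, was at 250 ± 23.8 and 447 ± 70.4 CPM, Ccl12 at 810 ± 287 and 269 ± 82.7 CPM and Pf4 at 1245 ± 297 and 571 ± 225 CPM, and the list did not move as a set (adjusted p = 0.814), but passed without pMCAO 2 (0.0487). Its median was -0.33 against -0.00 within the inferred blocks (adjusted p = 0.000965), a comparison of Sham 2 alone with pMCAO 1 and pMCAO 3. The chemokine scores of Sham 1 and Sham 2 (0.28 and 0.29) lay above those of Sham 3 and Sham 4 (-0.42 and -0.14), and that of pMCAO 2 (0.52) above all of them. Of 21 proinflammatory and NF-kB genes, 1 rose (the prostaglandin synthase Ptgs2, from 11.2 ± 2.20 to 33.0 ± 11 CPM) and 1 fell (Nfkb2, from 25.9 ± 5.80 to 12.9 ± 3.68 CPM) when adjusted over the list alone, 0 passed over all genes, and the list did not move as a set (adjusted p = 0.855). Of 19 complement genes, 7 rose and 4 fell when adjusted over the list alone and 0 passed over all genes (camera adjusted p = 0.855). Serping1, the C1 inhibitor, was at 5.0 ± 2.1 and 20.4 ± 10.2 CPM.

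Cell cycle genes lay lower as a set, and the calls for lists of lipid metabolism depended on the setting. Of 31 cell cycle genes, 27 had lower means, 9 fell and 1 rose when adjusted over the list alone and 0 passed over all genes, with a median log2 change of -0.74 (camera adjusted p = 3.44e-09, adjusted p = 0.218 with an estimated correlation, and adjusted p = 0.000143 within the inferred blocks, with a median of -0.78 from 1 sham library against 2). With the stromal marker score as a covariate the median was -0.38 (adjusted p = 0.010). The same pMCAO libraries had higher fibroblast markers, and the median of the replication-dependent histones was -0.92 (adjusted p = 0.704 with an estimated correlation). Mki67, the proliferation marker Ki-67, went from 282 ± 81.3 to 156 ± 20.5 CPM and the mitotic kinesin Kif11 from 27.6 ± 3.89 to 11.4 ± 2.65 CPM. Of 23 genes of cholesterol synthesis the median was -0.39 (camera adjusted p = 0.00141, and adjusted p = 0.327 with an estimated correlation), with 0 members passing over all genes or when adjusted over the list alone. This call was lost within the inferred blocks (median 0.05, adjusted p = 0.469), with sample quality weights (0.0722) and, at a median of -0.60 that lay further from 0, with the stromal marker score as a covariate (0.113). Of 20 genes of lipid efflux the median was 0.39 (camera adjusted p = 0.0132, and adjusted p = 0.616 with an estimated correlation). Mylip, a ubiquitin ligase induced by LXR, rose from 50.6 ± 7.61 to 90.2 ± 6.10 CPM when adjusted over the list alone, and 0 members passed over all genes. The lipid efflux call was lost without pMCAO 2 (adjusted p = 0.840) and within the inferred blocks (median 0.18, adjusted p = 0.852), with Y-linked counts as a covariate (median 0.19, adjusted p = 0.174) and with sample quality weights (0.116). Without pMCAO 3 its median was 0.60. The lipid efflux scores were 0.28, 1.13 and -0.01 in pMCAO 1, 2 and 3, and those of adipocyte markers were 1.33, 4.07 and -0.11. Whether adipocyte RNA moved the list was not tested.

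Genes of translation and respiration lay slightly lower. Of 77 cytosolic ribosomal protein genes the median log2 change was -0.33 (camera adjusted p = 3.44e-09) and of 76 nuclear genes of oxidative phosphorylation it was -0.43 (adjusted p = 2.12e-11), with 0 members of either passing over all genes or when adjusted over the list alone. With an estimated correlation the adjusted p were 0.616 and 0.602. Most of both shifts lay in pMCAO 3, where the mean log2 CPM of the members was below the sham mean by a score of -0.97 and -1.11, against -0.11 and -0.22 in pMCAO 1 and -0.07 and -0.14 in pMCAO 2. Without pMCAO 3 the adjusted p were 0.0534 and 0.00375 and the medians -0.11 and -0.15, and with offsets for GC content and exon length the medians were -0.11 and -0.21. Of 32 lysosomal genes, 2 rose and 2 fell when adjusted over the list alone and 0 passed over all genes, with a median of -0.33 (camera adjusted p = 0.0134, and adjusted p = 0.632 with an estimated correlation). This call was lost without Sham 2 (adjusted p = 0.0514) or pMCAO 3 (median -0.13, adjusted p = 0.181). It was also lost with offsets for GC content and exon length (median -0.09, adjusted p = 0.109) and with the stromal marker score as a covariate (median -0.15, adjusted p = 0.223). Gusb, beta-glucuronidase, went from 218 ± 27.2 to 131 ± 18.2 CPM. Within the inferred blocks the 3 medians were -0.68, -0.72 and -0.51 (adjusted p of 2.92e-14, 1.19e-16 and 0.000202), but these set Sham 2 alone against pMCAO 1 and pMCAO 3. Sham 2 had the highest ribosomal protein and oxidative phosphorylation scores of the sham libraries (0.19 and 0.18).

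**Figure D3:**
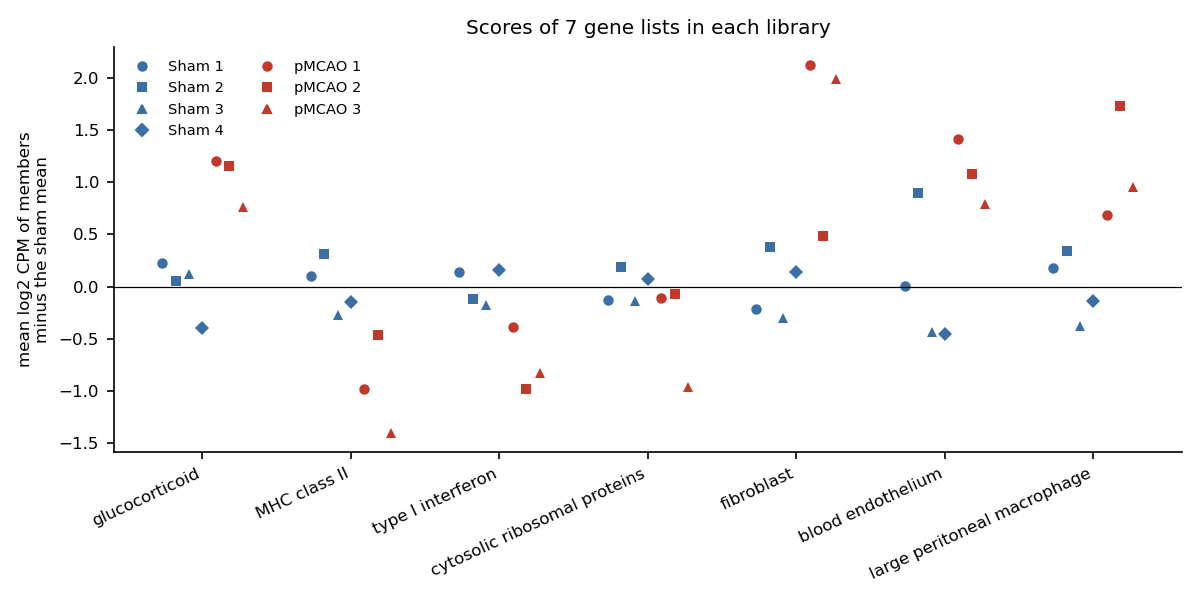
Mean log2 CPM of the members of 7 gene lists in each library, minus the mean of the 4 sham libraries (blue, sham, and red, pMCAO). The glucocorticoid scores of the 3 pMCAO libraries, 0.76 to 1.21, lie above all sham scores, while the ribosomal protein score stands apart in pMCAO 3 alone.

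Of the lists of markers of other cells, some lay higher after pMCAO and most did not move as sets. Of 14 blood endothelial markers, 9 rose when adjusted over the list alone and 0 passed over all genes, with a median log2 change of 1.08 (camera adjusted p = 7.14e-09, and adjusted p = 0.447 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, was at 37.8 ± 17.6 and 84.2 ± 2.06 CPM. The blood endothelial score did not separate the groups, as that of Sham 2 (0.89) lay above that of pMCAO 3 (0.80, two-sided exact permutation test, p = 0.114). Of 14 fibroblast markers, 7 rose when adjusted over the list alone and 0 passed over all genes, with a median of 1.89 (camera adjusted p = 1.98e-06, and adjusted p = 0.447 with an estimated correlation). The collagen genes Col1a2 and Col3a1 were at 7.15 ± 5.07 and 11.9 ± 6.32 CPM in sham libraries and at 30.6 ± 13.3 and 47.8 ± 29.3 CPM after pMCAO. Of 9 markers of large peritoneal macrophages, 4 rose when adjusted over the list alone and 0 passed over all genes, with a median of 1.70 (camera adjusted p = 0.00190, and adjusted p = 0.447 with an estimated correlation). Prg4, which encodes lubricin, was at 7.59 ± 2.63 and 30.2 ± 15.9 CPM. The median of this list was 0.74 with Y-linked counts as a covariate, 0.94 with the replicate block and 0.76 within the inferred blocks, from 1 sham library against 2. Of 5 lymphatic endothelial markers, 3 (Pdpn, Cp and Lyve1) rose when adjusted over the list alone and 0 passed over all genes. The camera adjusted p was 0.0248, and 0.447 with an estimated correlation. In sham libraries Cp was at 484 CPM against 0.57 CPM for Pdpn, and Lyve1 is also in the resident muscularis list. The rise of Cp and Lyve1 may thus not stem from lymphatic endothelium, and its source was not tested.

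Of 4 adipocyte markers 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0289, and adjusted p = 0.676 with an estimated correlation), and Cfd, which encodes adipsin, was at 0.997 ± 0.906 and 21 ± 32.4 CPM. Of 11 replication-dependent histone genes, whose transcripts lack a poly(A) tail, 0 passed over all genes or when adjusted over the list alone, with a median of -0.92 (camera adjusted p = 0.0248, and adjusted p = 0.704 with an estimated correlation). Within the inferred blocks, where Sham 2 is the only sham library, the fibroblast call held (median 1.67, adjusted p = 8.19e-08). The lymphatic call did not, at a median as large (0.73, adjusted p = 0.0619), nor did that of the histones (-0.77, 0.0992). The blood endothelial (0.39, 0.201), peritoneal macrophage (0.76, 0.227) and adipocyte (0.88, 0.546) calls were lost with medians that shrank by over 1.5 times, from 1.08, 1.70 and 2.84. The lymphatic call was lost without pMCAO 1 (adjusted p = 0.111) and with the stromal marker score as a covariate (median 0.15 against 0.72, adjusted p = 0.524), the adipocyte call without pMCAO 2 (0.648), and the histone call without Sham 4 (0.0809), pMCAO 1 (0.139) or pMCAO 3 (median -0.57, adjusted p = 0.199), without scaling factors (0.0507) and with the replicate block (median -0.74, adjusted p = 0.153). The adipocyte call was also lost with Y-linked counts as a covariate (median 1.31, adjusted p = 0.0708) and with sample quality weights (0.0604), while its median was 4.67 (adjusted p = 2.40e-06) with the stromal marker score, and the lymphatic call over genes of at least 5 CPM (0.212). The fibroblast score was 2.12, 0.48 and 1.99 in pMCAO 1, 2 and 3 and lay between -0.30 and 0.38 in sham libraries. Of the listed markers, 12 of 14 blood endothelial, 8 of 14 fibroblast, 3 of 9 peritoneal macrophage, 3 of 5 lymphatic and 2 of 4 adipocyte genes were at 5 CPM or more in sham libraries, and 1, 0, 5, 1 and 2 of them are in another list.

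Measures of library composition also differed. The share of counts from the mitochondrial ribosomal RNAs was 3.6% ± 1.51 (SD, n = 4) in sham libraries and 9.88% ± 2.33 (SD, n = 3) after pMCAO. The two-sided exact permutation test gave p = 0.057, the smallest that its doubled form can give for 4 against 3 libraries. The 10 most abundant genes took 10% ± 1.24 and 15.7% ± 2.36 of the counts (exact permutation test, p = 0.057). Across 9774 genes, which are not independent replicates, the log2 change correlated with GC content (Spearman's rho = -0.561) and with exon length (rho = 0.320). A smooth trend on GC content and exon length took up 38.8% of the variance of the log-ratios in pMCAO 3, 22.5% in Sham 4, 17.2% in Sham 2 and at most 7.73% in the other libraries.

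**Figure D4:**
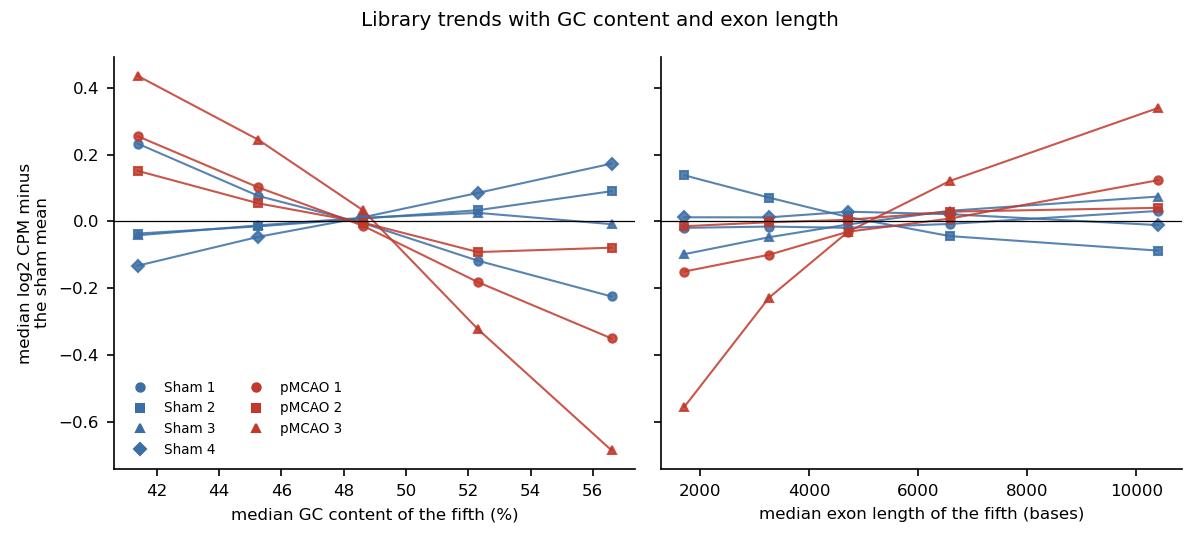
Median log2 CPM minus the sham mean in 5 bins of genes by GC content (left, %) and by exon length (right, bases), 1 line per library (blue, sham, and red, pMCAO). The steepest lines are those of pMCAO 3, from 0.44 in the bin with the lowest GC content to -0.68 in that with the highest.

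The other program lists did not pass as sets over all libraries. Camera gave adjusted p of 0.860 for heat shock and chaperone genes, 0.144 for the unfolded protein and integrated stress response, 0.855 for oxidative stress (NRF2) targets, 0.860 for hypoxia and glycolysis, 0.0683 for mitochondrially encoded genes, 0.872 for efferocytosis and scavenger receptors, 0.855 for iron handling, 0.855 for secreted factors that support neurons and tissue, 0.855 for pattern recognition receptors, 0.515 for leukocyte adhesion and migration and 0.855 for apoptosis and p53 targets. The mitochondrially encoded list passed without Sham 1 (0.00782) or pMCAO 3 (0.00261), over genes of at least 5 CPM (0.0199) and with sample quality weights (0.000561). The hypoxia list passed with the stromal marker score as a covariate (median 0.37 against -0.01, adjusted p = 0.0374) and the unfolded protein list over genes of at least 5 CPM (0.0314). No member of these lists passed over all genes. When adjusted over the list alone, Slc7a11, the cystine transporter, rose in both stress lists (1.23 ± 1.10 to 9.49 ± 3.6 CPM), and Dnajb9 rose from 153 ± 19.3 to 265 ± 60.8 CPM. Pfkp, a phosphofructokinase, fell from 44.8 ± 14.6 to 22.6 ± 0.938 CPM, and Ddit4 rose from 36.5 ± 16.6 to 115 ± 17.1 CPM in the hypoxia list. Msr1, a scavenger receptor, rose from 414 ± 28.8 to 629 ± 91.3 CPM and Gas6, a ligand of Mertk, fell from 435 ± 118 to 247 ± 5.58 CPM. Of 22 secreted factors 1 rose and 4 fell when adjusted over the list alone, among them Pdgfb, which went from 37.7 ± 6.04 to 18.8 ± 3.52 CPM. Of 24 pattern recognition receptors, 2 rose (Clec7a and Clec4d) and 1 fell (Tmem173, which encodes STING, from 100.2 ± 12 to 64.4 ± 5.46 CPM). Of 22 adhesion genes 2 fell, S1pr2 and Selplg, a selectin ligand. No heat shock, mitochondrially encoded, iron handling or apoptosis gene passed when adjusted over the list alone.

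Markers of neutrophils (camera adjusted p = 0.915), classical monocytes (0.413), dendritic cells (0.192), T cells (0.941), B and plasma cells (0.788), NK cells and innate lymphoid cells (0.788), mast cells (0.781), eosinophils (0.482), enterocytes (0.284), goblet, Paneth and enteroendocrine cells (0.850), smooth muscle (0.175), enteric glia (0.326), interstitial cells of Cajal (0.781), mesothelium (0.241), erythrocytes (0.788), and platelets (0.899), and nuclear and RNA polymerase III RNAs (0.596), did not pass as sets over all libraries. No member of these lists passed over all genes. When adjusted over the list alone, Cdh19 rose among glial markers (1.23 ± 1.02 to 8.54 ± 4.39 CPM) and Pf4 fell among platelet markers. Enteric neuron markers (2 measured) and exocrine pancreas markers (1 measured, Cela1, at 2.66 ± 1.62 and 0.443 ± 0.230 CPM) were too few to test. Within the inferred blocks the T cell median was -1.51 against -0.49 (adjusted p = 0.000549), from Sham 2 alone against pMCAO 1 and pMCAO 3. The T cell score of Sham 2 (0.85) lay far above those of Sham 3 (-1.22) and Sham 4 (-0.605) and close to those of Sham 1 (0.98) and pMCAO 2 (0.70), while pMCAO 1 and pMCAO 3 were at -0.68 and -0.52. The classical monocyte list passed without pMCAO 3 (median 0.49 against 0.27, adjusted p = 0.000172), without Sham 1 (0.0439) and with sample quality weights (0.00879). Smooth muscle passed without Sham 1 (0.0346) or Sham 2 (0.00585) and with sample quality weights (0.00557). Interstitial cells of Cajal passed with Y-linked counts as a covariate (0.000320), sample quality weights (0.0188), the replicate block (0.0344) and without pMCAO 2 (0.0347). Without Sham 1, the B and plasma cell and enterocyte lists passed (0.0420 for each), as did enterocytes with the stromal marker score (0.00111). With Y-linked counts as a covariate dendritic cells (0.0357), enteric glia (0.0262) and the goblet, Paneth and enteroendocrine list (0.0262) passed, the last also with the replicate block (0.00899). The sign of the median differed from the direction of the camera test for the B and plasma cell, erythrocyte, platelet, NF-kB, NRF2, hypoxia, secreted factor and pattern recognition lists, and the sign of the mean alone for the heat shock, iron handling, NK cell, mast cell and enterocyte lists.

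The authors' deposited table called 14 genes at an FDR under 0.05, of which 4 were higher and 10 lower after stroke. H2-Eb1 was the only gene called in both that table and the present test. The log2 fold changes in the authors' deposited table were -2.73 for H2-Eb1, -2.34 for H2-Ab1, -2.22 for Cd74 and -2.42 for Ccl12, against -1.78, -1.41, -1.45 and -1.59 in the present fit. The mitochondrial ribosomal RNA mt-Rnr2 was at 2.04 in the authors' deposited table and 1.63 here (adjusted p = 0.0504). Ccl5, a chemokine, was at -2.25 in the authors' deposited table and -0.00 here. The deposited fold changes weigh almost only Sham 2 against pMCAO 1 and pMCAO 3 (weights of -0.998, 0.435 and 0.561), while the present fit uses all 7 libraries. Differences between them are therefore not differences over the same libraries. Across 17209 genes, which are not independent replicates, the fold changes of the authors' deposited table and of the present fit had a Pearson r of 0.673 and a Spearman rho of 0.716, and 79.9% had the same sign.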

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

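The check for a library far from the others was run on 207 results in the 4 sham libraries, since groups of 3 are too small for it. It was first run on a smaller set that held no such value and was then extended to all named genes. It marked 10, a total about what chance gives at 1 in 20, and all 10 are log2 CPM values of single genes. Of these, 8 lay in Sham 1, so the total alone does not show that chance spread them over the libraries. Psmb9, an immunoproteasome subunit, was at 5.64 in Sham 3, against 6.33 to 6.35 in the other sham libraries. Ddit4, a stress gene induced by glucocorticoids, was at 3.57 in Sham 4, against 5.40 to 5.56. The other 8 lay low in Sham 1: Ndufa9 at 4.21, Rpl18 at 6.17, Apoe at 11.8, Gusb at 7.47, Cd300ld at 8.28, Blvrb at 6.18, Mmp9 at 5.89 and Cp at 8.48. Each of the 10 outlying values is low and pulls the sham mean of its gene down. Sham 1 also had the highest mitochondrial ribosomal RNA share of the sham libraries, 5.82% against 2.42% to 3.23%. No explanation was tested for these values.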

How the results depend on the processing

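The 4 added settings (GC content and exon length offsets, Y-linked counts, the stromal score and the library block) were chosen after seeing the data. All 17 changed genes kept their direction in every setting run, 16 of them being measured under the filter of 5 CPM. They were chosen from the same libraries with no overlap between groups, so most settings could hardly turn their direction. The cause of no change below was tested unless its construction shows it. The count of genes changed (higher and lower) was 34 (24 and 10) with upper-quartile factors, 29 (14 and 15) without factors, 75 (49 and 26) over genes of at least 5 CPM, 476 (284 and 192) with DESeq2, 35 (24 and 11) with limma-voom, 818 (551 and 267) with sample quality weights, 43 (29 and 14) after thinning to the smallest library and 98 (65 and 33) at a threshold of 0.10. Of the added settings, GC content and exon length offsets gave 28 (11 lower), Y-linked counts 38 (35 and 3), the stromal score 0 (0 and 0) and the library block 2 (0 and 2, H2-Ab1 and H2-Eb1, of which H2-Ab1 is outside the rule for named genes). Leaving out each library in turn gave 0 to 100 genes, 0 to 75 higher and 0 to 25 lower, 11 to 16 program lists and 4 to 10 marker lists. The 9 genes without Sham 4 include 8 of the 17 and the 7 without pMCAO 3 include 5. With a replicate block the count was 21, 11 higher and 10 lower, of which 11 are among the 17. Same-numbered libraries deviated with r of -0.117, 0.0494 and 0.18 for replicates 1, 2 and 3, against means of 0.0513, -0.0204 and -0.0669 with other numbers. These values give no clear sign of pairing, but 3 correlations are too few to exclude it. The unfiltered setting removed no gene and tests nothing, and a pseudocount was not varied because counts were tested.

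Program lists past the threshold numbered 0 with an estimated correlation and 0 with fry, against 16, and 10 with the library block. They numbered 11 with sample quality weights and 11 with Y-linked counts as a covariate, which ended the calls of the alternatively activated, interferon-gamma, immediate early, lipid efflux and clock lists, and among markers that of adipocytes. Marker lists numbered 0, 0 and 3, against 6. The direction turned for the interferon-gamma list with quality weights (adjusted p = 0.816), for B and plasma cells with the replicate block (0.00344), and for alternatively activated genes (0.824) and NK and innate lymphoid cells (0.0114) with the library block. With the stromal score as a covariate it turned for mast cells (0.0161), smooth muscle (0.0416), interstitial cells of Cajal (0.0416), blood endothelium (0.782), fibroblasts (0.561) and histones (0.0805); the score is made of the fibroblast and endothelial lists, so the turns of these lists follow from its construction, and the cause was not tested for the others. The highest adjusted p over all settings was that with an estimated correlation for the called lists other than those that turned and these: 0.863 for alternatively activated genes, 0.997 for immediate early genes, 0.469 for cholesterol synthesis, 0.852 for lipid efflux and 0.524 for lymphatic endothelium. Over the planned settings, all named genes were the same in 3131 cases, gained a call in 204 and lost one in 47. Lists were the same in 921, gained in 19, lost in 78 and turned in 2. Over the added settings the genes were the same in 669, gained in 13 and lost in 38. Of the 180 named genes, only the 17 called ones could lose a call, and a gene called in neither fit counts as the same. The totals of same cases therefore do not measure stability. The lists were the same in 178, gained in 8, lost in 22 and turned in 8. The unfiltered setting, which tests nothing, gave 180 and 54 of the same cases. In the simulation, the procedure recovered 38% of the genes of at least 5 CPM changed 2-fold, at this depth and number of libraries. Changes of that size may therefore often be missed.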

Other observations

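The tests of the library blocks, of dilution, of stromal RNA for the antigen presentation and interferon genes, of the change of each member under offsets for GC content and exon length, and of pMCAO 3 alone were chosen after the results were seen, and the block test of the antigen presentation and interferon genes was divided by list after the combined result was seen. The dilution test was divided by list after its combined result was seen, and took the place of one on the resident muscularis list, which had argued against dilution but whose members went both ways. The bounds on SE between libraries were 2 SE at first and were replaced by the points of t for the residual degrees of freedom when the class II value was known, which leaves open a dilution that 2 SE would have excluded for class II. A bound on the ratio of medians was also tried after the first results and met or missed the bound in the same tests as the preset one. The SE of medians and of median changes below are bootstrap SE over member genes, which are not independent. They do not measure the spread between libraries unless that is stated.

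Some complement genes were higher and others lower when adjusted over the complement list alone, while the list did not move as a set (camera adjusted p = 0.855) and no member passed over all genes. Of the 19 measured, 7 rose and 4 fell over the list alone, and those named here were chosen after their values were seen. C1qa, C1qb and C1qc, the chains that start the classical pathway, fell by 0.97, 0.92 and 0.78 on the log2 scale, and properdin (Cfp), which stabilises the alternative pathway convertase, fell by 0.93. C3, the central component, rose from 54.9 ± 7.58 to 110 ± 71.8 CPM, and the inhibitors Cd55 from 40.5 ± 15 to 66.4 ± 12.6 CPM, Cd59a from 7.59 ± 2.16 to 14.5 ± 5.9 CPM and Serping1 by 2.02 on the log2 scale. Serping1 and C3 are also expressed by fibroblasts, whose markers were higher in the same libraries. Within the cell cycle list, Pcna, the sliding clamp of DNA replication and repair, rose from 129 ± 13.3 to 190 ± 22.7 CPM when adjusted over the list alone, against 9 members that fell.

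The higher glucocorticoid list is the first pattern, with a median log2 change of 0.92, and of its 26 members 9 are in another list and 21 are at 5 CPM or more in sham libraries. A trend with GC content and exon length is argued against as the whole cause: the offsets changed the members' log2 changes by a median of 0.164 (SE 0.0537), away from 0, and left the list median at 0.885 (SE 0.361, adjusted p = 6.54e-18), while they brought the ribosomal protein median from -0.33 to -0.11. The SE over members kept that median from passing the preset bound of 0.5 times the uncorrected median by 2 SE, so the argument rests on the change of each member. The sort for GFP at the Cx3cr1 locus would limit RNA from stromal cells, but their markers were still measured after it. The endothelial gene Cdh5 was at 37.8 CPM in sham and 84.2 CPM in pMCAO libraries. Stromal RNA stays open, with a median of 0.669 (SE 0.293, camera adjusted p = 9.42e-06) and a mean list score higher by 1.01 (SE 0.43 between libraries) with the stromal score as a covariate. Library blocks stay open, because the median of 0.789 within them (SE 0.272, adjusted p = 0.000469) sets 1 sham library against 2, and an effect of pMCAO also stays open.

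The lower class II and type I interferon lists are the second pattern, with a median of -0.751. For the pooled lists, a trend with GC content and exon length is argued against as the whole cause. The median was -0.670 after correction (SE 0.0747) and the median change of each member 0.0715 (SE 0.0513). This test was not divided by list. With the offsets the class II median was -0.858 (SE 0.148, before -1.11) and that of interferon -0.604 (SE 0.0627, before -0.660), so the argument is weaker for class II. Dilution by RNA of other cells, which would lower all macrophage transcripts alike and which the same sort would limit, stays open, because the score minus the pan-macrophage score differed between the groups by -0.495 for class II (SE 0.239 between libraries) and -0.274 for interferon (SE 0.257), where 5 residual degrees of freedom ask for 2.57 SE. The class II difference was 2.08 SE in size, and pMCAO 2 (-0.17) lay above Sham 3 (-0.26) and Sham 4 (-0.28). The exact permutation test by absolute difference gave p = 0.171. With the stromal score as a covariate the medians were -1.06 (SE 0.17, adjusted p = 2.58e-06) for class II and -1.06 (SE 0.29, adjusted p = 1.33e-09) for interferon, against -1.11 and -0.660 without it, but the score differences of -0.949 and -1.01 had SE of 0.595 and 0.360 between libraries, too wide to exclude stromal RNA. Library blocks stay open for the same reason as above, with medians within them of -1.89 for class II (SE 0.382, before -1.11), where Sham 2, the sham library with the highest class II score, is the whole sham arm, and -0.409 for interferon (SE 0.188, before -0.660), as does an effect of pMCAO.

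The lower ribosomal protein and oxidative phosphorylation lists are the third pattern, with a median of -0.356. Without pMCAO 3 the median was -0.122 (SE 0.0164 over members, highest camera adjusted p of the pair 0.0534), which is under 0.5 times the uncorrected value. The pattern may thus rest mostly on that library, whose description names a pool. Over all libraries the score differences were -0.38 (SE 0.26 between libraries) for ribosomal proteins and -0.49 (SE 0.27) for oxidative phosphorylation. With GC content and exon length offsets the median was -0.165 (SE 0.0228, highest adjusted p 0.00104) and the median change of each member 0.208 (SE 0.0185), both too close to the bound to decide. Within the library blocks the medians were -0.68 and -0.72, from a single sham library. An effect of pMCAO on these genes remains open and untested beyond this.

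Of the 35 ways to part the 7 libraries into 4 and 3, 1 (the real one) gave 17 genes or more. The highest count of the others was 3. A share of 1 in 35 argues against chance for the gene count only if the libraries are free to change places. This is the smallest share the test can give, the splits move libraries across the inferred blocks, and with the block the count was 2. For program lists 1 of the 35 gave 16 or more, but the others reached 14 and none gave fewer than 4, so the list test with a preset correlation calls lists readily in libraries parted at random. For marker lists 20 of the 35 gave 6 or more, up to 12, so chance cannot be excluded for that count.

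The authors' deposited fold changes and p-values were matched to within 5.44e-14 and 3.05e-14 by limma-voom with TMM factors and a block of 4 levels: Sham 1, then Sham 2 with pMCAO 1 and pMCAO 3, then Sham 3 with Sham 4, then pMCAO 2. The division was found after the deposited values were seen and after exploratory fits, by comparing all 790 divisions by least squares and refitting the 12 closest, and the next closest differed by up to 0.0400 in log2 and 0.422 in p. What the blocks stand for is not in the labels. In that fit, with 2 residual degrees of freedom, the weights of the libraries on a fold change were -0.998 for Sham 2, 0.435 for pMCAO 1 and 0.561 for pMCAO 3, and at most 0.003 in size for each of the others, so Sham 2, pMCAO 1 and pMCAO 3 carry the comparison.

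The libraries differ in transcripts that mark sex, which the labels do not give. The summed CPM of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y was 335, 10.97, 238 and 0.726 in Sham 1 to Sham 4 and 2.21, 558 and 215 in pMCAO 1 to pMCAO 3, and Xist was at 1589, 4100, 3585, 5709, 5595, 1.34 and 4833 CPM in the same order. Both kinds of transcript lay above the level of 3 counts in every library. In Sham 1, Sham 3 and pMCAO 3 both were at 215 CPM or more, and Sham 2, the sham library of the block comparison, held Xist with Y-linked transcripts at 10.97 CPM. Whether such libraries are pools of animals of both sexes is not in the labels and was not tested.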
